A study of Homo sapiens with 34 samples.

How the data were processed

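Total RNA of 34 established non-small cell lung cancer (NSCLC) cell lines, grown to log phase, was compared on Agilent arrays with 2 dyes with an in-house mix of RNA from 45 NSCLC lines pooled in equal amounts, per the labels. Each line was hybridised once, so no line had a replicate and 1 array stood for each line. The growth protocol gave the medium of each line: 23 lines in RPMI1640, 5 in ACL4, 4 in HITES, A549 in Ham's F12 and Calu-3 in EMEM. Samples were read as 34 lines of 1 kind compared with the mix, and the medium was used for a second comparison. No line was grown in more than 1 medium, so medium and line identity could not be separated.

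The authors deposited a scanner table for each array, which holds, per the file headers, the intensity of each spot in the green and the red channel (mean over pixels) and the median intensity of its local background, with no normalization. The same tables hold the scanner software's own log10 ratio of red over green after its background correction and dye normalization, per the file headers. The authors' deposited value table holds log10 ratios too: every column correlated at 0.99999 or more with the scanner log10 ratio of its array averaged over the spots of a probe, with the same scale and direction. Its column medians ran from 0.00128 to 0.0256, so the columns had not been centred on 0 again. Agilent Feature Extraction was version 9.5.1 per the submitters' processing notes while the file headers name another version, and the difference stays open. The genome build behind the probe design was not given in the sources used here, so no coordinates are printed.

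The labels name Cy5 for both channels, which left the direction of the ratio open. By a rule set before the data were examined, the channel more alike between arrays was read as the mix. Green was the more alike on 34 of 34 arrays, with a mean correlation over the 561 array pairs of 0.988 ± 0.00609 (SD) against 0.892 ± 0.0235 for red. Red was therefore read as the cell line, which makes the direction likely rather than stated. No pair of arrays had a log ratio correlation under -0.0407 over all probes.

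Values were computed from the intensities in R 4.3.3 with limma version 3.58.1 and data.table version 1.17.8. Background was corrected with normexp and an offset of 50, arrays were normalized within themselves by loess with control spots and outlier spots at weight 0, spots of 1 probe were averaged, and the probe with the highest average brightness stood for its gene. Each array held 22153 spots with 20173 gene probes, of which 100 were spotted 10 times. Probes well above background in either channel on at least 4 arrays were kept. That filter removed almost nothing, because 99.98% of the negative control spots carried the well-above-background mark in green and 18.25% in red. Symbols came from the accession in the scanner table for 16433 probes and from the symbol for 1514, through a RefSeq gene table of assembly GRCh38.p14. For 1459 probes the name in the file was kept, and 767 carried no gene name and appear under their identifier. XIST, related X-inactivation genes and Y-linked genes were removed before any test, and 18337 genes remained. Families with near-identical members (AKR1C, MAGEA, GAGE, XAGE, CTAG, HLA, HBA, HBG, MT1, PSG) can share probe signal, and values of single members are uncertain.

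The comparisons in this paragraph were fixed before the data were examined, with those alternatives that are said below to have been fixed in advance. Lines were compared with the mix by limma's moderated test of the intercept with Benjamini-Hochberg adjustment at 0.05, for genes, and by camera with a preset correlation of 0.01 for 28 fixed lists holding 406 different genes. Genes with an SD over the lines above 1 on the log2 scale, and genes at least 4-fold from the mix in each line, were counted without a test. List scores, the mean log2 ratio of the measured members of a list, were correlated over lines in 15 fixed pairs with two-sided permutation tests of 100000 draws. Where mclust 6.1.1 preferred 2 clusters to 1 by over 10 BIC units, the correlation was taken within the larger cluster. Another 18 fixed pairs of a line and a gene or list were tested by the exact rank of the line among 34. Lines in ACL4 and HITES (9) were compared with those in RPMI1640 (23) by limma and camera. The mix entered as 1 RNA, so its own spread is in no test, and p-values measure the spread between lines.

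Genes were named by a rule set at the same time. It took the 10 genes with the highest and the 10 with the lowest mean log2 ratio among those past the threshold with 1 sign in at least 28 of 34 lines, and the 20 genes with the largest SD. It also took the 10 genes with the largest gap between the highest and the next line (1 per line), 2 to 4 members of each list described, the fixed pairs, and for the medium the 5 genes of smallest p if none passed. A few genes, fixed pairs and 1 list that the rules pick are left out of the text, while counts and adjusted p-values still include them. Genes named outside the rule are said to have been chosen after their values were seen.

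The statistical tests were tried on simulated data made from the normalized values of the real arrays, with 200 of 18337 genes shifted. Background correction, loess and a constant bias of a probe were not simulated, so the figures say nothing about them. For lines against the mix, genes were centred and whole arrays changed sign at random, which does not keep the skew of genes high in few lines. For lines against the mix, 62% of genes shifted by 0.25 on the log2 scale were recovered, 89.5% at 0.5 and 99.5% at 1, with 16, 9 and 5 unchanged genes called. For the medium, 55% were recovered at 0.5, 82.5% at 1 and 98.5% at 2, with 4, 10 and 0 unchanged genes called. For the medium lists, over the same 18337 genes, camera with the preset correlation found a list of 18 genes shifted by 0.5 but also called 2 unchanged lists. With an estimated correlation it found 0% of the shifted list.

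The median spot intensity per array ran from 96.6 to 182.5 in green and from 96.8 to 217.57 in red, and the share of gene probes brighter than the negative controls from 71.5% to 89.5% in green and from 62.8% to 97.2% in red. Replicate spots of 1 probe had a median SD of 0.06 on the log2 scale per array, from 0.05 to 0.10. No 2 arrays held identical values. For these arrays, their number limits the precision. Arrays fell on 5 extraction days in 3 sessions of 28, 3 and 3 arrays. The day on which the software extracted the image was used in place of the scan day, and was treated as a batch. Figures were drawn with python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

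Alternatives fixed in advance were the scanner's log ratio, the deposited value table, median centring in place of loess, Aquantile after loess, all probes of a gene averaged, 2 other filters on dim probes, the day as a block, a test of the linear ratio, other thresholds, camera with an estimated correlation, fry, and subsets of lines for the medium. Filters and a background taken from negative control spots, and fits without chosen arrays, were added after the data were seen. Lists lacked, among others, NCAM1, KRT6A, MUC5AC, MUC5B, PIFO, AKR1C2, RET, SPRED2, CTAG1B, XAGE1A, HSPA1B, HSPA4, ANKRD37 and IDI1, which matched no kept gene.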

Results

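Expression of 18337 genes was measured in 34 NSCLC cell lines, established cultures from the most common class of lung cancer, each on 1 array against a mix of RNA from 45 NSCLC lines. Values are log2 ratios of a line to the mix, and 0 marks equal signal. The lines were grown in RPMI1640 (23 lines), in the hormone-supplemented media ACL4 (5) and HITES (4), in Ham's F12 (A549) or in EMEM (Calu-3). Serum differed with the medium: HITES held 5% FBS, ACL4 held 10% FBS for 3 lines and 2% BSA without FBS for H2286 and H2405, and the other media held 10% FBS. The arrays fell on 5 extraction days, with 7, 13 and 8 arrays on the first 3 days and 3 on each of the others.

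The first comparison asked how single lines differed from the mix. S100A8 and S100A9, which form calprotectin, averaged -3.85 ± 0.20 (SE, n = 34) and -3.43 ± 0.27, and were lower than the mix in 33 and 32 of 34 lines. The chemokine CXCL14 averaged -3.81 ± 0.23, the fibrinogen gamma chain FGG -3.49 ± 0.30, the adhesion protein CEACAM6 -3.39 ± 0.44, the natriuretic peptide precursor NPPB -3.15 ± 0.15, the keratin KRT23 -3.02 ± 0.28 and the aldo-keto reductase AKR1B10 -2.99 ± 0.35. The transcripts listed as W60781 and ENST00000223214 averaged -4.51 ± 0.35 and -3.48 ± 0.27, the latter above the negative controls in only 26 of 34 lines, so that its mean is a bound. All 10 had adjusted p-values of 1.63e-07 (CEACAM6) or less by limma.

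Several of these low genes had lines far above the others. CEACAM6 stood at 4.05 in H2110 and 3.71 in H1793, against a median of -4.59. CXCL14 stood at 3.60 in H520, FGG at 3.58 in H1944 and 2.71 in H2110, KRT23 at 4.28 in Calu-3, and AKR1B10 at 2.56 in A549 and 2.16 in H1944. A saturated spot gives only a lower bound, and W60781 and CXCL14 had 1 line and AKR1B10 had 2 lines with such a spot. When ratios were averaged on the linear scale before the log, CEACAM6 came to 0.26, W60781 to -0.63, FGG to -0.70 and KRT23 to -0.34, while S100A8 stayed at -2.99 and NPPB at -2.37.

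Genes higher in the lines than in the mix differed by much less. Among genes past the threshold with 1 sign in at least 28 lines, BPNT1, a bisphosphate nucleotidase, was highest at 0.87 ± 0.09 (SE, n = 34; higher in 33 lines), followed by the nucleolar GTPase GNL3L at 0.65 ± 0.10 and the nuclear pore protein NUP43 at 0.62 ± 0.08. The zinc finger genes ZNF175 and ZNF652 averaged 0.58 ± 0.07 and 0.57 ± 0.08, MPHOSPH8, a protein of heterochromatin, 0.55 ± 0.07, and SLC23A3, of the vitamin C transporter family, 0.53 ± 0.04. LENG8, the ubiquitin ligase RNF125 and the RNA cleavage factor CSTF2T averaged 0.52 ± 0.04, 0.52 ± 0.08 and 0.51 ± 0.11. For RNF125 the mix channel was above the negative controls on only 18 of 34 arrays, so its mean is uncertain. All 10 passed limma's test, with adjusted p-values from 1.59e-12 for SLC23A3 to 0.000317 for CSTF2T. Averaged on the linear scale before the log, they stood from 0.54 for LENG8 to 0.98 for BPNT1. SLC23A3 and LENG8 were higher in all 34 lines, with SDs of 0.23 and 0.24. A constant bias of a dye or probe would also give this, and was not tested for these genes. The transcript listed as ENST00000361624, named after its value was seen, averaged 0.73 ± 0.14 but was higher in only 25 lines.

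Of 18337 genes, 7321 differed from the mix (limma, adjusted over all genes), 4430 higher and 2891 lower, and 8771 had an unadjusted p under the threshold. Only 768 also differed by at least 1.5-fold on average, of which 764 were lower and 4 higher. With each array centred on its median in place of loess, 13831 genes differed (8177 higher, 5654 lower), and of the 2578 that differed by at least 1.5-fold 2209 were higher and 369 lower, so the side of the large differences turned. A test of the linear ratio called 4711 genes higher and 1199 lower. Of these, 14 had a mean ratio at least the log2 of 1.5 away from 1 (4 higher, 10 lower). That cut is stricter than 1.5-fold, above all on the lower side. Without a test, the linear mean was at least 1.5 times the mix for 81 genes and at most 1/1.5 of it for 97.

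Of the 28 lists, 20 passed camera with a preset correlation and all 20 lay on the lower side. With the correlation estimated from the data 0 of the 20 calls held, while fry, which asks whether the genes of a list move on balance 1 way, called 22 lists lower and 1 higher. With median centring in place of loess, 1 of the 20 stayed past the threshold (fibroblast, adjusted p = 0.017), and the cholesterol synthesis, glucocorticoid response and selenoprotein lists turned to the higher side without passing.

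Of 22 epithelial genes, 20 were lower than the mix and 0 higher (20 and 0 adjusted over the list alone; camera adjusted p = 6.68e-07, adjusted p = 0.212 with an estimated correlation). The protease PRSS8 averaged -2.31 ± 0.35 (SE, n = 34), the adherens junction protein CDH1 -1.73 ± 0.42, the keratin KRT19 -1.70 ± 0.37 and MAL2 -1.51 ± 0.40. List counts here and below rest on mean log ratios. Averaged on the linear scale before the log, CDH1 came to 0.04 and MAL2 to 0.13, so these were not lower than the mix on that scale. The mesenchymal gene COL1A1 stayed lower at -0.54. Of 21 measured mesenchymal genes, 14 were lower and 1 higher (14 and 1 adjusted over the list alone; camera adjusted p = 2.46e-06, adjusted p = 0.144 with an estimated correlation). The collagen COL1A2 averaged -2.44 ± 0.26, the matrix protein SPARC -2.41 ± 0.31 and fibronectin FN1 -2.07 ± 0.30, and ZEB1, a repressor of CDH1, was the higher member at 0.27 ± 0.09. Of 9 fibroblast genes, which share COL1A1 and COL1A2 with that list, 7 were lower and 1 higher, with the same counts adjusted over the list alone (camera adjusted p = 1.28e-05, adjusted p = 0.0524 with an estimated correlation); COL3A1 averaged -2.37 ± 0.33, and DCN was the higher member at 0.10 ± 0.04.

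Of 20 measured neuroendocrine genes, 11 were lower and 2 higher (12 and 2 adjusted over the list alone; camera adjusted p = 0.00463, adjusted p = 0.427 with an estimated correlation). The calcitonin gene CALCA averaged -2.74 ± 0.37 and gastrin-releasing peptide GRP -2.55 ± 0.36. CHGB, DDC and UCHL1, the members among the 20 genes of largest SD, averaged -1.49, -1.45 and -1.17. Averaged on the linear scale before the log, they came to 1.11, 1.05 and 0.10, so these were not lower than the mix on that scale. The other members are not given on it. Of 14 alveolar type II genes, 8 were lower and 0 higher (8 and 1 adjusted over the list alone; camera adjusted p = 0.000226, adjusted p = 0.0524 with an estimated correlation); FOXA2 averaged -1.29 ± 0.32 and the aspartic protease NAPSA -1.02 ± 0.10. Of 13 measured squamous or basal genes, 6 were lower and 1 higher (the same adjusted over the list alone; camera adjusted p = 0.0151, adjusted p = 0.222 with an estimated correlation), with SOX2 at -1.83 ± 0.31 and TP63 at -1.26 ± 0.25. Of 11 measured secretory airway genes, 6 were lower and 2 higher (6 and 3 adjusted over the list alone; camera adjusted p = 0.0123, adjusted p = 0.144 with an estimated correlation), with the trefoil peptide TFF1 at -2.34 ± 0.17 and AGR2 at -2.06 ± 0.36.

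Of 20 measured NRF2 targets, genes of the oxidative stress response, 11 were lower and 0 higher (15 and 0 adjusted over the list alone; camera adjusted p = 2.46e-06, adjusted p = 0.212 with an estimated correlation), with HMOX1 at -1.83 ± 0.26. Of 17 interferon response genes, 12 were lower and 0 higher (13 and 0 adjusted over the list alone; camera adjusted p = 0.000198, adjusted p = 0.222 with an estimated correlation), with IFI27 at -2.30 ± 0.34 and MX1 at -1.23 ± 0.22. Of 12 MHC class I genes 9 were lower and 1, the peptide transporter TAP2, higher at 0.10 ± 0.02 (the same adjusted over the list alone; camera adjusted p = 0.00265, adjusted p = 0.291 with an estimated correlation). Of 9 MHC class II genes 6 were lower and 0 higher (6 and 2 adjusted over the list alone; camera adjusted p = 0.000113, adjusted p = 0.212 with an estimated correlation), with HLA-DRB1 at -1.65 ± 0.18.

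Of 7 EGFR ligands, 3 were lower and 0 higher (4 and 0 adjusted over the list alone; camera adjusted p = 0.00747, adjusted p = 0.144 with an estimated correlation): AREG averaged -2.64 ± 0.41 (n = 33), EREG -1.50 ± 0.33 and NRG1 -1.31 ± 0.17. Of 14 measured genes of ERK output, 8 were lower and 0 higher, also over the list alone (camera adjusted p = 0.000411, adjusted p = 0.172 with an estimated correlation), with the phosphatase DUSP6 at -1.03 ± 0.30. Of 23 measured receptor tyrosine kinases, 6 were lower and 1 higher, also over the list alone (camera adjusted p = 0.0393, adjusted p = 0.212 with an estimated correlation); ERBB2 averaged -1.93 ± 0.27, and NTRK2 was the higher member at 0.22 ± 0.06. Of 16 measured cancer-testis antigens, 4 were lower and 0 higher, also over the list alone (camera adjusted p = 0.00281, adjusted p = 0.222 with an estimated correlation), with PAGE5 at -1.72 ± 0.20.

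Of 16 measured hypoxia and glycolysis genes, 6 were lower and 0 higher, also over the list alone (camera adjusted p = 0.00337, adjusted p = 0.212 with an estimated correlation), with ENO1 at -0.49 ± 0.11. The cholesterol synthesis list had 7 lower and 0 higher of 18 measured, also over the list alone (camera adjusted p = 0.000513, adjusted p = 0.235 with an estimated correlation), with MVD at -0.57 ± 0.09. The glucocorticoid response had 6 lower and 1 higher of 15 (8 and 2 adjusted over the list alone; camera adjusted p = 0.00747, adjusted p = 0.144 with an estimated correlation), with MT2A at -1.46 ± 0.28. Selenoproteins had 8 lower and 0 higher of 15, also over the list alone (camera adjusted p = 0.000936, adjusted p = 0.144 with an estimated correlation), with SELENOP at -1.07 ± 0.23. The estrogen response had 5 lower and 2 higher of 10, also over the list alone (camera adjusted p = 0.0406, adjusted p = 0.144 with an estimated correlation), with TFF1 and AREG the lowest.

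The other 8 lists did not pass camera, and 7 of them are described here. Proliferation genes had 1 lower (CCNB2, -0.24 ± 0.09, n = 33) and 1 higher (MCM4, 0.45 ± 0.11) of 20, adjusted p = 0.528, and heat shock genes 1 lower (HSP90B1, -0.28 ± 0.11) of 14, adjusted p = 0.323. With median centring both of these lists passed on the higher side (adjusted p = 0.00498 and adjusted p = 0.00302). The SWI/SNF list had 2 lower and 2 higher of 14 (adjusted p = 0.718), ciliated airway genes 1 lower (FOXJ1, -0.33 ± 0.11) and 1 higher of 8 (adjusted p = 0.843), leukocyte genes 2 lower (LCP1 and ITGB2) and 1 higher of 12 (adjusted p = 0.296), endothelial genes 2 lower and 1 higher of 8 (adjusted p = 0.258), and erythroid genes 1 lower and 2 higher of 7 (adjusted p = 0.528). Adjusted over the list alone, proliferation kept 0 lower, heat shock 0 lower and leukocytes 0 higher members, and the other counts were the same. The mean and the median differed in sign for the ciliated, proliferation, SWI/SNF and leukocyte lists, with the mean below 0 and the median above.

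The second question was how much the lines differed from each other. Among the 20 genes that varied most, the chemokines CXCL1 and CXCL2 had SDs of 2.90 and 2.41 on the log2 scale (n = 34 lines), and CXCL1 ran from -6.26 in H2135 to 3.37 in H460. The cancer-testis genes XAGE1, XAGE3, MAGEA2B and CTAG1A had SDs of 2.88, 2.87, 2.49 and 2.40, and XAGE1 and XAGE3 were highest in H810 and H1975. The epithelial surface genes EPCAM, CDH1 and MAL2 had SDs of 2.83, 2.48 and 2.36, and CEACAM6 2.62. EPCAM ran from -5.68 in H2172 to 2.45 in H1435.

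The fibulin EFEMP1 (SD 2.69), osteopontin SPP1 (2.67) and the protease inhibitor TFPI2 (2.67) were highest in H460 at 2.80, in H1944 at 2.89 and in H2286 at 3.63. The G protein subunit GNG11 had an SD of 2.60, the hypoxia factor EPAS1 2.44, and the EGFR ligand AREG 2.40 with its highest value of 3.49 in A427 (AREG, XAGE1 and UCHL1 each had 1 line with a saturated spot). The neuroendocrine genes CHGB, UCHL1 and DDC had SDs of 2.47, 2.43 and 2.42, with CHGB at 4.73 in H1385 and DDC at 4.15 in SHP77.

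Of all genes, 1160 had an SD above 1 and 317 above 1.5, and the median SD was 0.34. With the scanner's own log ratio 1773 genes had an SD above 1, and with the deposited values 1772 did.

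Lines were also compared in pairs by their log2 ratios over all 18337 genes, not only those that varied most. The median r between the log2 ratios of 2 lines was 0.203 over the 561 pairs, H522 and H1581 had 0.590, and H1385 and H596 had -0.0448. H2135 and H810 had 0.862, with 41 genes at least 4-fold apart, and they were grown in RPMI1640 and HITES.

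**Figure D1:**
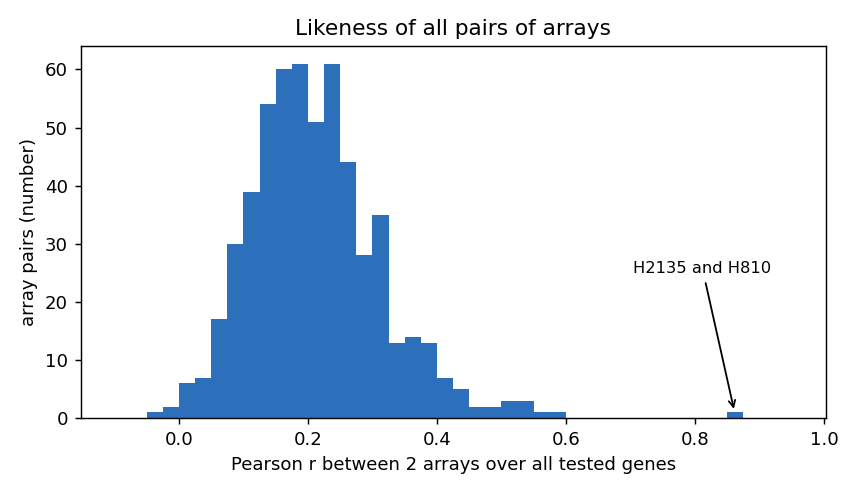
Pearson's r of log2 ratios between the arrays of 2 lines, as a histogram over all 561 pairs of the 34 lines. The pair of H2135 and H810, marked by the arrow, stands at 0.862, and the next pair at 0.590.

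Some genes were high in 1 line. CXCL14 in H520 stood at 3.60, with -2.70 in the next line, H1435. RHOXF2, a homeobox gene of the germline, stood at 4.02 in H1299, FDCSP at 3.25 in Calu-3, the germline gene MAEL at 4.44 in H358 and the collagen COL1A1 at 4.05 in Calu-1. The heart and neural crest factor HAND2 stood at 3.95 in H1581, the matrix protein SPARCL1 at 4.39 in H1793, the kainate receptor GRIK1 at 3.60 in SHP77 and the glucuronosyltransferase UGT2B4 in H1944 stood 4.08 above the next line. The transcript listed as ENST00000296723 stood at 4.95 in H460.

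A line had a median of 283.5 genes at least 4-fold from the mix, of which 60 were higher and 225.5 lower in the median line, and all 34 lines had more lower than higher genes. H1836 had most (155 higher, 547 lower), then H522 (60 and 488) and SHP77 (161 and 372), and H2073 had fewest (62 and 124). The H1836 array also had the highest median intensity in both channels (182.5 in green, 217.57 in red), the most saturated red spots (53) and the largest share of probes above the negative controls in red (97.2%). The H2073 array had the largest SD between replicate spots (0.10) and the most outlier spots (83) of all arrays. Whether this bears on its low count was not tested. H1385 had most higher genes, 202, and H23 fewest, 14. With median centring the split of the median line turned to 193.5 higher and 152 lower, and with the scanner's log ratio the median rose to 480 genes (100 higher, 375.5 lower). There was 1 array per line, so none of these counts has an error.

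**Figure D2:**
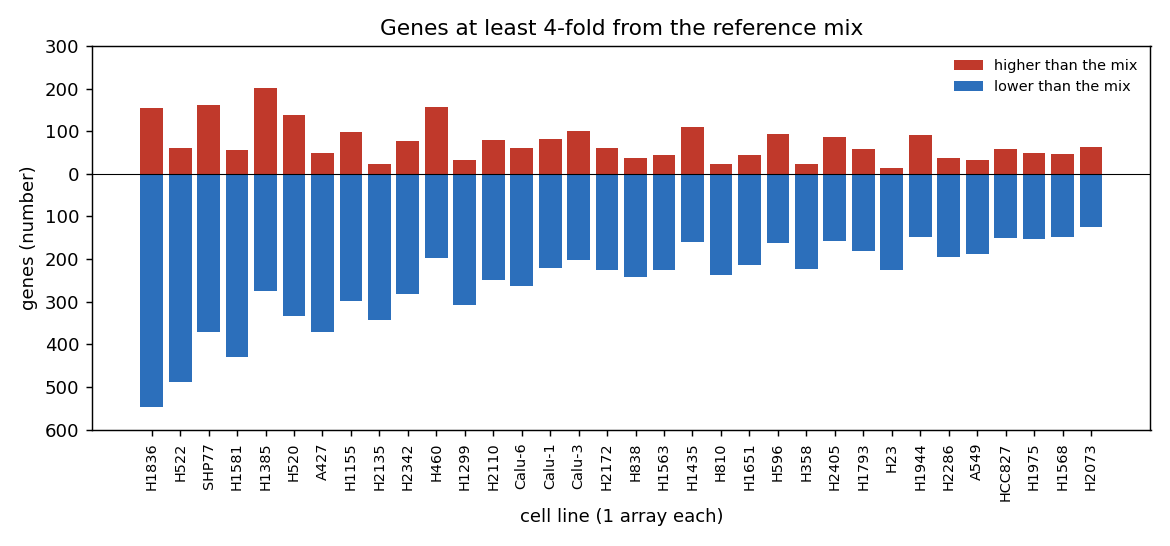
Number of genes at least 4-fold from the mix in each of the 34 lines (1 array each, so no error bars), with genes higher than the mix above the zero line in red and lower genes below it in blue. H1836 reaches 702 genes and H2073 186, and the lower bar is the longer in all 34 lines with the loess values shown.

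List scores described single lines. H2342 had the highest epithelial score, 1.31, led by MAL2 (2.27), CDH1 (2.18) and the splicing factor ESRP2 (2.10), followed by H1435 at 0.94, HCC827 at 0.93 and Calu-3 at 0.81. H1299 had the lowest, -2.40. Calu-1 stood apart on the mesenchymal score at 1.58, with COL1A1 at 4.05, SPARC at 2.96, the transcription factor SNAI2 at 2.73 and the collagen cross-linker LOX at 2.72, and the next line, H1563, had 0.06.

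Neuroendocrine scores fell into 2 clusters by mclust, with H1385 (2.81), SHP77 (2.38), H1836 (1.73) and H1155 (1.04) in the upper. In H1385 the calcitonin gene CALCA reached 5.23, CHGB 4.73, SCG5 4.70 and GRP 4.57. SHP77 had GRP at 4.82 and CALCA at 4.68, and H1836 had the transcription factor INSM1 at 4.43 with CALCA at -3.83. H1155 had NEUROD1 at 3.35. H1385 and H1836 were on the fifth extraction day with H2073, which had a score of -0.87. SHP77 and H1836 are catalogued elsewhere as small cell lung cancer lines, while the labels give all 34 lines as NSCLC.

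NRF2 targets were highest in H1944 at 1.48, led by the transporter ABCC2 (2.49), AKR1C3 (2.33) and GCLM (2.27), then in A549 at 1.18, H1793 at 0.99 and H460 at 0.42. H596 had the highest interferon score, 1.89 (MX1 2.74, IFIT2 2.65), and the highest MHC class I score, 1.58 (TAP1 2.56, PSMB9 2.44). MHC class II was highest in Calu-1 at 1.04, H596 at 0.65 and Calu-3 at 0.64. H596 also led the squamous or basal score at 0.72, with S100A2 at 3.64 and TP63 at 2.62. H2110 led the secretory airway score at 0.42 with AGR2 at 3.08, and the alveolar type II score at 0.10 with CEACAM6 at 4.05 and surfactant protein SFTPD at 2.02. H838 and H1299 led the cancer-testis score at 1.04 and 0.90, both with GAGE1 high (2.92 and 3.33). HCC827 had the highest leukocyte score, 0.65, with LCP1 at 2.33 and PTPRC at 2.29.

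**Figure D3:**
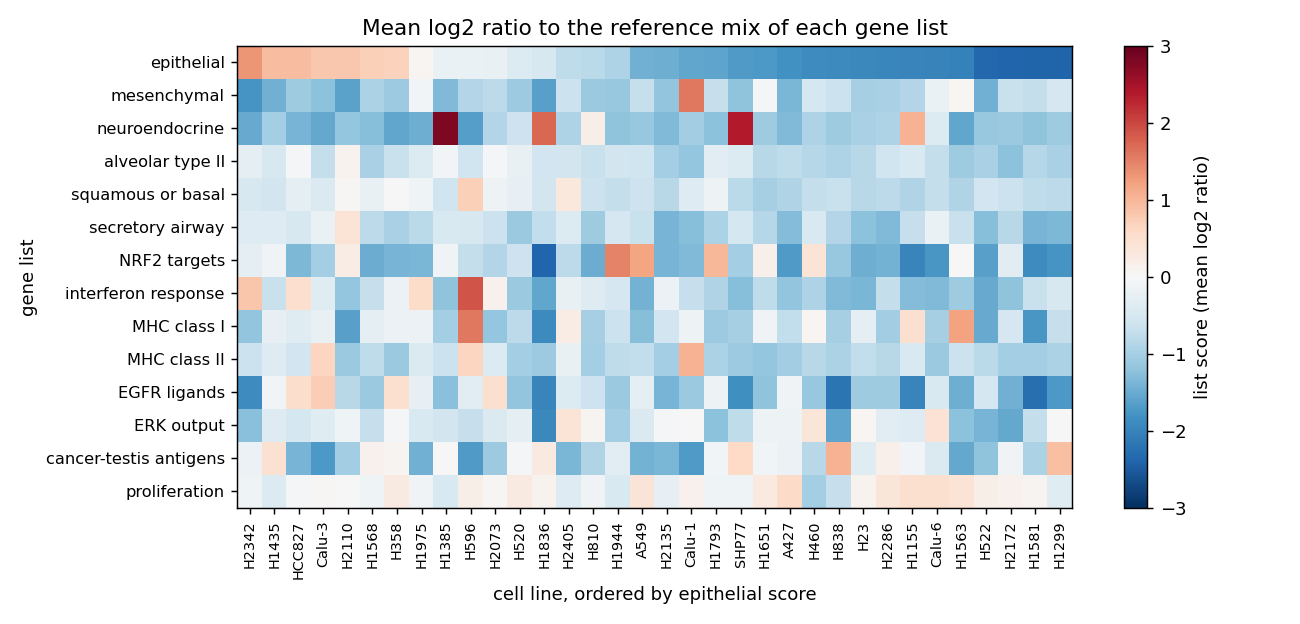
List scores (mean log2 ratio to the mix of the measured genes of a list, colour scale from -3 to 3) for 14 lists in rows and 34 lines in columns, ordered by epithelial score, 1 array per line. Red squares for neuroendocrine genes stand at H1385, SHP77, H1836 and H1155, and the red square for mesenchymal genes at Calu-1.

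Lines with more CDH1 had less ZEB1. Over the 34 lines Pearson's r was -0.647 (permutation p = 3e-05, adjusted p = 0.00045 over 15 relations) and Spearman's rho -0.607 (permutation p = 0.00014). Without H2342 and HCC827, the extremes on CDH1, r was -0.579. Within the first 3 extraction days r was -0.843, -0.567 and -0.634. ERBB3, a receptor of the EGFR family, also ran against ZEB1, with r = -0.557 (permutation p = 0.00064, adjusted p = 0.0024) and rho = -0.457 (permutation p = 0.00709). Without 2 lines r was -0.450, and within days it was -0.806, -0.504 and 0.323, so it did not hold on day 3.

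**Figure D4:**
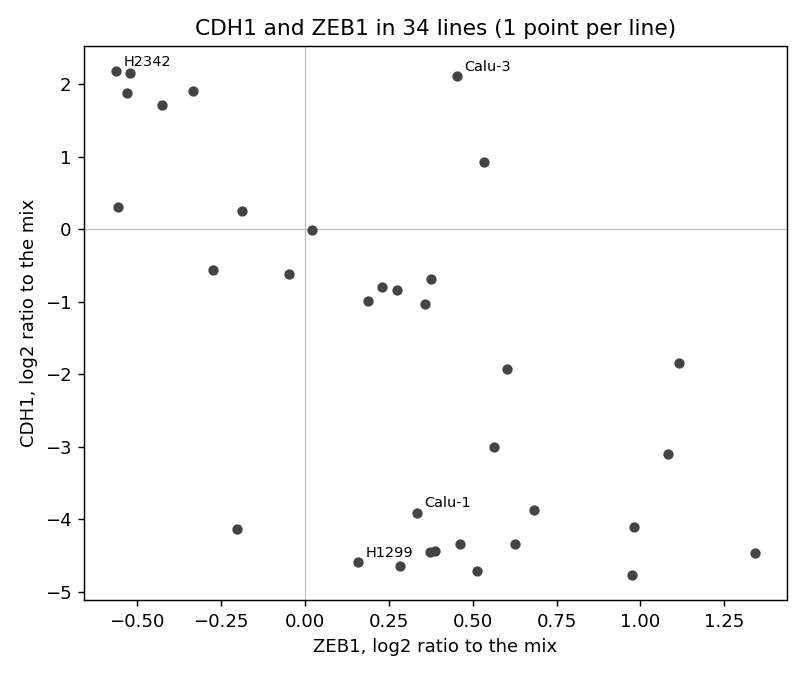
CDH1 against ZEB1, both as log2 ratios to the mix, 1 point per line (34 lines, 1 array each). Pearson's r is -0.647, and Calu-3 stands off the trend with CDH1 at 2.11 and ZEB1 above 0.

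Epithelial scores rose with scores of differentiated lung epithelium. With alveolar type II genes r was 0.584 (permutation p = 0.00032, adjusted p = 0.0016) and rho 0.596 (permutation p = 0.00027). With squamous or basal genes r was 0.571 (permutation p = 0.00029, adjusted p = 0.0016) and rho 0.679 (permutation p = 3e-05), and with secretory airway genes r was 0.546 (permutation p = 0.00084, adjusted p = 0.00252) and rho 0.534 (permutation p = 0.0015). Without 2 lines these were 0.570, 0.641 and 0.508. Within the first 3 days r was 0.863, 0.6005 and 0.277 for alveolar genes, 0.611, 0.835 and 0.796 for squamous genes, and 0.652, 0.532 and 0.113 for secretory genes. When the median member replaced the mean, r fell to 0.218 for alveolar and 0.246 for secretory genes, and neither passed.

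The other 4 relations that passed did not pass an unadjusted test of r without their 2 extreme lines. EGFR ligands rose with the epithelial score (r = 0.459, permutation p = 0.00693, adjusted p = 0.0173; rho = 0.467, permutation p = 0.006), and without Calu-3 and HCC827 r was 0.337 (permutation p = 0.0597). The epithelial and mesenchymal scores ran against each other (r = -0.398, permutation p = 0.017, adjusted p = 0.0318; rho = -0.477, permutation p = 0.00448), and without H2342 and H1435 r was -0.303 (permutation p = 0.0891). The interferon score rose with MHC class I (r = 0.419, permutation p = 0.0155, adjusted p = 0.0318; rho = 0.330, permutation p = 0.0585), and without H596 and H2342 r was 0.270 (permutation p = 0.134). Within the 31 lines outside the MHC class II cluster of Calu-1, Calu-3 and H596, the interferon score rose with MHC class II (r = 0.401, permutation p = 0.0256, adjusted p = 0.0427; rho = 0.2996, permutation p = 0.101), and without H2342 and H1975 r was 0.299 (permutation p = 0.115). With day means removed r was 0.448, -0.380 and 0.389 for the first 3 of these, all of which kept a permutation p under the threshold. The EGFR ligand relation and that of interferon with MHC class II ended with the median of members, and both interferon relations ended with median centring, that with MHC class II also with the scanner's log ratio. None of the first 3 kept its sign within all of the first 3 days: r was -0.321, 0.652 and 0.656 for EGFR ligands, -0.726, -0.374 and 0.189 for the mesenchymal score, and -0.590, 0.390 and 0.540 for MHC class I.

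The remaining 6 relations did not pass. EGFR ligands and ERK output had r = 0.343 (permutation p = 0.047, adjusted p = 0.0705; rho = 0.317). NRF2 targets and proliferation had r = -0.282 (adjusted p = 0.143; rho = -0.294), but with day means removed r was -0.377 (permutation p = 0.0272), which passed. With the median of members, EGFR ligands with ERK output passed too (r = 0.411). Cholesterol synthesis and proliferation had r = -0.161 (adjusted p = 0.420; rho = -0.214). Heat shock and proliferation had r = -0.0733 (adjusted p = 0.681; rho = -0.0500). Within the 30 lines outside the neuroendocrine cluster, the neuroendocrine score had r = -0.272 with the epithelial (adjusted p = 0.184; rho = -0.297) and r = 0.0806 with the mesenchymal score (adjusted p = 0.681; rho = 0.180). The 4 lines of the cluster are too few for a correlation, and so are the 3 arrays of each of the last 2 days.

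In all, 18 pairs of a line and a gene or list, known from textbooks as amplified, deleted or active, were looked up. Calu-3 ranked first on the receptor gene ERBB2 at 3.63, against -2.10 ± 1.28 (SD, n = 33) in the other lines. H520 ranked first on the receptor gene FGFR1 at 2.01 (others -0.81 ± 1.11) and on the transcription factor SOX2 at 3.29 (others -1.99 ± 1.65). A427 was lowest on the cell cycle inhibitor CDKN2A at -2.72 (others -0.39 ± 1.32), and H1944 highest on NRF2 targets at 1.48 (others -0.90 ± 0.87). Second ranks were held, among others, by HCC827 on EGFR at 2.30, behind H1568 at 2.52, by SHP77 on neuroendocrine genes and by A549 on NRF2 targets.

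Other pairs ranked lower. H1581 ranked 3 on FGFR1 at 1.23 and A549 ranked 3 from below on the methylthioadenosine phosphorylase MTAP at -1.33. H1155 ranked 4 on neuroendocrine genes, H460 ranked 4 on NRF2 targets and A549 ranked 4 from below on CDKN2A at -2.27. H460 ranked 8 on CDKN2A at -2.11, and H838 ranked 18 on NRF2 targets at -1.14. The smallest exact one-sided p of a rank among 34 lines is 0.0294, and 0 of the 18 pairs passed after adjustment (smallest adjusted p = 0.106 for the 5 first ranks, all of which had an unadjusted p under the threshold).

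**Figure D5:**
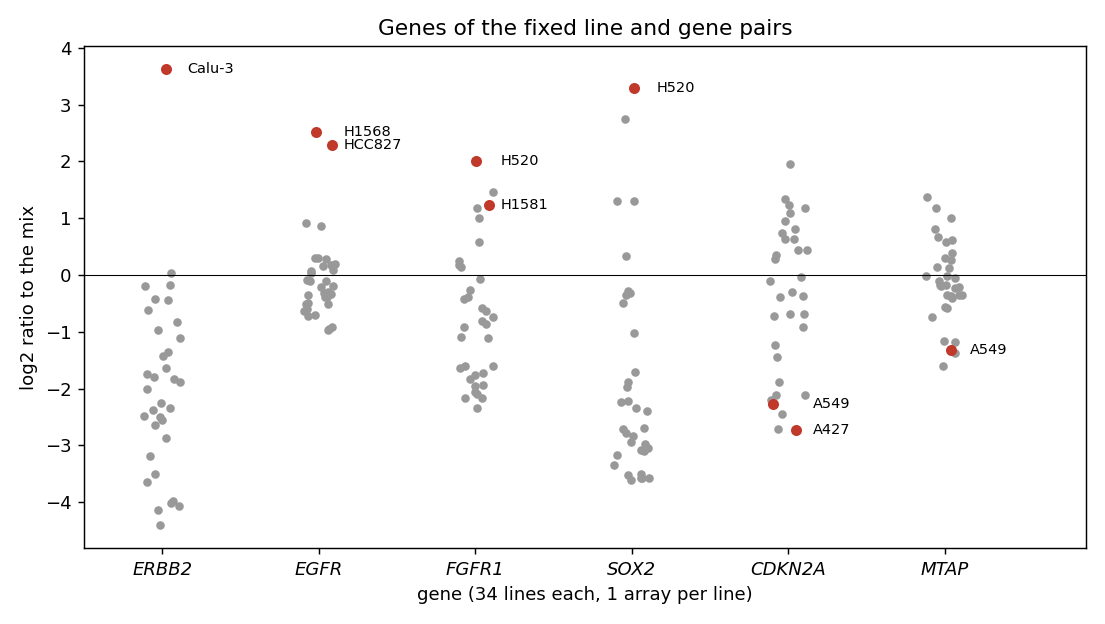
Log2 ratio to the mix of 6 genes of the fixed pairs, 1 point per line (34 lines per gene, 1 array each, points spread sideways for visibility only), with named lines in red and the others in grey. Calu-3 stands at 3.63 on ERBB2 and H520 at 3.29 on SOX2, each above all other lines.

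The last comparison asked whether lines in the hormone-supplemented media ACL4 and HITES (9) differed from lines in RPMI1640 (23). By camera with the preset correlation 3 lists passed, none of which has a member that passed over all genes. The mean shift of the hypoxia and glycolysis list was -0.20 (adjusted p = 0.0056; adjusted p = 0.739 with an estimated correlation; 0 of 16 members), with the glycolytic enzymes ALDOA at -0.66 ± 0.20 (SE) and LDHA at -0.43 ± 0.28 and the peptide ADM at -0.68 ± 0.61. The MHC class I shift was -0.36 (adjusted p = 0.00797; adjusted p = 0.934 with an estimated correlation; 0 of 12 members), with B2M at -0.65 ± 0.54 and the immunoproteasome subunit PSMB9 at -0.52 ± 0.28. The neuroendocrine shift was 0.40 (adjusted p = 0.0336; adjusted p = 0.934 with an estimated correlation; 0 of 20 members), with DDC at 1.69 ± 0.93, INSM1 at 1.42 ± 0.87 and CALCA on the other side at -0.79 ± 0.88.

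None of the 3 list calls held by fry (adjusted p = 0.667, 0.905 and 0.905). With the extraction day as a block the shifts were -0.34, -0.66 and 0.44. Within days 1, 2, 3 and 5 they were -0.23, -0.31, -0.33 and -0.60 for hypoxia and glycolysis, -0.60, -0.73, -0.52 and -0.82 for MHC class I, and -0.44, 0.58, 0.64 and 0.76 for neuroendocrine genes. These days held 1, 2, 2 and 1 hormone-media lines against 6, 10, 5 and 2 lines in RPMI1640. The lone lines were H2342 on day 1 and H1836 on day 5. Without H1836 all 3 calls ended. Its array was the brightest, and it is catalogued elsewhere as a small cell line. H1836 had the lowest MHC class I (-1.915) and hypoxia and glycolysis (-0.83) scores of all 34 lines, and a neuroendocrine score of 1.73. Without H1155, without H810, or without H810 and H2135 the neuroendocrine call ended, and without H1581 the MHC class I call. The MHC class I call also ended with median centring (adjusted p = 0.0608) and the neuroendocrine call with the stricter filter on both channels (adjusted p = 0.0680). With ACL4 lines only all 3 calls ended, and with HITES lines only all 3 held. H810 is the HITES line whose array was most like another one, that of the RPMI1640 line H2135, and the neuroendocrine scores of H810 and H2135 were 0.18 and -1.33.

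No single gene differed between the media (limma, 0 genes, also with robust eBayes and a trend), while 1103 had an unadjusted p under the threshold and 917 would by chance alone. The smallest p-values belonged to genes that did not pass. The cytochrome c oxidase assembly factor SCO1 differed by -0.83 ± 0.17 (SE; adjusted p = 0.533), with 0 of 9 hormone-media lines above the RPMI1640 median. RIMKLA differed by 1.04 ± 0.26, the mitochondrial histidyl-tRNA synthetase HARS2 by -0.35 ± 0.09 and the glutamate receptor subunit GRIN3A by 0.33 ± 0.08, each with adjusted p = 0.747. Adjusted over the list alone, the SWI/SNF subunits SMARCC2 (0.50 ± 0.17) and SMARCB1 (0.32 ± 0.09) and the ciliary gene RSPH1 (0.82 ± 0.24) were higher and ALDOA lower, and none of these passed over all genes.

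The other 25 lists did not pass. Glucocorticoid response genes came nearest, with a shift of -0.30 (adjusted p = 0.0543; adjusted p = 0.739 with an estimated correlation), and with the extraction day as fixed block this list passed as a 4th (adjusted p = 0.0265). SGK1 and DUSP1, both induced by glucocorticoids, stood at -1.16 ± 0.49 and -1.47 ± 0.61. Mesenchymal genes had a shift of -0.37 (adjusted p = 0.0996), with the matrix protein TGFBI at -2.05 ± 0.78. Selenoproteins shifted by 0.02 (adjusted p = 0.903) and estrogen response genes by -0.06 (adjusted p = 0.735). The mean and the camera direction differed in sign for the estrogen response, squamous, endothelial and proliferation lists, and the mean and the median for the estrogen response, secretory airway, SWI/SNF and proliferation lists.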

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

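No test in this part was chosen after its result was seen. The 28 list scores and the number of genes at least 4-fold from the mix were searched, among the lines in ACL4, those in HITES and both together, for 1 line far from the rest of its group by the ratio of its gap to the group's range. H1155 had a neuroendocrine score of 1.04 among 5 lines in ACL4, the nearest being at -0.93. H1836 had a proliferation score of 0.10 among 4 lines in HITES, the nearest being at -0.12, and H1793 a SWI/SNF score of -0.49 among the same lines, the nearest being at 0.00. Of the 87 combinations tested 3 passed, and chance alone would pass about 1 in 20, or 4.35.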

How the results depend on the processing

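The filter and the background based on negative control spots, and the fits without sessions 2 and 3, without H810, and without H810 and H2135, were chosen only after the data had been seen. Single results other than the main counts stayed the same 1674 times, moved 75 times, lost the threshold 69 times, gained it 20 times and reversed 6 times. Where no reason is given, the cause was not tested. With median centring, 13831 genes and 3 lists differed from the mix. The proliferation list (adjusted p = 0.00498), heat shock (adjusted p = 0.00302), cholesterol synthesis (adjusted p = 0.472), glucocorticoid response (adjusted p = 0.964) and selenoproteins (adjusted p = 0.784) turned to the higher side. As a mean linear ratio minus 1, CEACAM6 turned to 0.195. At least 1.5-fold from the mix were 768 genes, fewer by construction, and 317 genes had an SD above 1.5. With the scanner's log ratio 1773 genes had an SD above 1, with the deposited values 1772, and the median count of genes 4-fold from the mix was 480 with both. The gene count against the mix was 5683 with the day as a random block, 6764 without sessions 2 and 3, 7153 without H810 and 5910 on the linear ratio. The correlations that passed numbered 6 to 10 over all settings, and first ranks 4 to 7.

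Camera with an estimated correlation left 0 lists against the mix and 0 for the medium, and fry left 0 for the medium. HITES lines alone gave 6 lists, and leaving out each hormone-media line in turn gave 0 (H1836) to 5 (H1435, H2405). For the medium, 0 genes passed in every fit over all days, and 89, 5 and 1 within days 1, 2 and 3, where 1, 2 and 2 hormone-media lines remained. Day 1 had the lone line H2342, assumed to vary like the others. A comparison within day 4 could not be made, because it held ACL4 lines only. Aquantile leaves log ratios as they are and gave 7318 genes against the mix, and leaving out the filter on dim probes gave the same 7321, since that filter removes almost no gene. Only 87 genes were above the negative controls in no line. No paired analysis was possible because all lines form 1 group and the replicate numbers only name samples.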

Other observations

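The tests on genes lower than the mix, the other splits for the gene count by medium, the splits within extraction days and the shuffling of line labels were chosen only after the result was seen. Receptor kinase genes stood out in single lines, chosen here after their values were seen. KIT, the stem cell factor receptor, was at 3.49 in H1435 and 3.05 in H1836, and ALK at 3.08 in H520 and 2.56 in HCC827. MYCL, a MYC family gene, was highest in H1836 at 1.09. In SHP77 the low genes included BTG3, an inhibitor of proliferation, at -5.30, and the nuclear receptor partner NRIP1 at -2.89, both relative to the median line.

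Neighbouring genes of 1 family moved together in several lines, again relative to the median line. Pregnancy-specific glycoprotein genes were high in H2172 (PSG11 5.56, PSG6 4.91), Calu-1 and H1568, CXCL chemokines in H2405 (CXCL1 7.29, CXCL5 5.93), Calu-3 and H460, and metallothioneins in H1975 (MT1M 4.88), H2286 and Calu-1. The guanylate-binding proteins GBP3 and GBP4 stood at 3.71 and 3.25 in H596, the line with the highest interferon score. Probes of such families can share signal, so their members are not separate evidence.

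Genes at least 1.5-fold from the mix were nearly all lower, 764 of 768, with loess but not with median centring, where 2209 of 2578 were higher. A pool made on the linear scale would exceed the average log value of genes high in few lines, and the median over the 764 genes rose from -0.93 to -0.225 when ratios were averaged on the linear scale. Of the 764 genes, 489 had a line at least 4-fold above the mix. Pooling in equal amounts, which the labels state, puts the mean log ratio of such genes below the log of their mean ratio. On the linear mean 151 of the 764 genes lay above 0. Over all genes 97 were at least 1.5-fold lower and 81 at least 1.5-fold higher on it, so the nearly one-sided split was not seen on that scale. The exact share of the pattern that pooling accounts for was left open, since the bound, set after the data were seen, was missed narrowly. A dye bias of the probes stays open: the median SD over lines of these genes was 1.326 against 0.34 for all genes, but a constant bias would leave the SD as it is. Mix lines that are not on these arrays may account for part: 97 of the 764 genes stayed at least 1.5-fold lower on the linear mean, too few for the whole pattern and too many to dismiss.

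The arrays of H2135 and H810 were far more alike than any other pair (r = 0.862, next pair H522 and H1581 0.590, median 0.203). Of 44 genes higher in H2135 than in the 32 other lines and at least 4-fold above their median, 95.5% were at most 2-fold lower in H810, and 87.8% of 41 in reverse, but such shares follow from the likeness itself, so whether 1 line was grown under both names stays open. The same RNA on both arrays was unlikely, since the cell line channel differed 2.613 times as much as the mix channel, although no other pair had a smaller cell line difference (SD 0.33, others from 0.60). A shared extraction day was no cause either, since the arrays were of different days and pairs within a day exceeded other pairs by only 0.0175 in median r. Of 41 genes at least 4-fold apart, 40 were higher in H810, among them INSM1 (3.13 against -2.81) and DDC (2.67 against -2.56), and adding a share of H1385 to H2135 lowered the difference by at most 10.3%, which left a mixture open.

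Whether high genes sat among high neighbours was tested on the 10 nearest measured genes in the order of assembly GRCh38.p14. All gene values in this paragraph are relative to the median line, not to the mix. Calu-3 ranked 1 of 34 around ERBB2 (STARD3 3.63, GRB7 3.56) and HCC827 ranked 1 around EGFR (SEC61G 4.71, VOPP1 3.13), which is in line with a gain of the region, though no DNA was measured. Around FGFR1, H520 ranked 2 (TACC1 1.30, NSD3 1.25), which decides nothing, while H1581 ranked 5 (DDHD2 1.53, NSD3 1.24). H520 ranked 7 around SOX2 (DNAJC19 1.27) and A427 ranked 11 from below around CDKN2A (IFT74 -0.81, CDKN2B -0.215). In these last 3 the mean of the 10 neighbours did not stand out, although single neighbours were raised or low. Neighbours with little signal in the median line could not fall further, so a loss around CDKN2A could be missed. Over the genome 62 runs of 9 genes passed the threshold from shuffled gene order, 38 high and 24 low, but only 16 and 5 held fewer than 3 genes with 1 name stem, among them a run with USP35, NDUFC2 and ALG8 in H1435 (3.95, 3.62, 3.38) that also holds KCTD14 and KCTD21. Shuffled line labels gave 5 or more first ranks among the 18 pairs with a share of 0.00022, so the first ranks were more than chance would give.

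The comparison of media was set against splits of the 32 lines into groups of the same sizes, 100 with the real one included. All 100 gave at least as many genes as the 0 found, which any split must, with 3 the highest, and 14 gave at least the 1103 genes with an unadjusted p under the threshold (highest 1622, median 794). For lists, 82 gave at least the 3 found, with 12 the highest. With splits made within extraction days and the day as a block, 67 of 100 gave at least the 4 lists found, with 13 the highest, so chance could not be excluded for the list calls by medium. Some splits called several times the real number of lists. This may come from a structure among the lines or from camera's preset correlation of 0.01, and neither was tested on the splits. The correlation estimated from the data was 0.59 for the neuroendocrine, 0.57 for the MHC class I and 0.19 for the hypoxia and glycolysis list.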
